A study of Mus musculus with 4 samples.

How the data were processed

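Gene expression was measured in 4 libraries of sorted macrophages of C57 BL/6J mice, 1 each from quadriceps, diaphragm, peritoneum and lung. Per the labels' protocols, muscle was digested with collagenase B and dispase II, cells were enriched over Lympholyte-M and sorted by CD45, CD11b, F4/80 and CD64, and the 4 libraries were made on 1 chip with the 10X Genomics Chromium chemistry for transcript ends, version 2. The same protocol text is attached to every library, and how peritoneal and lung cells were obtained is not given separately in the sources used here. The deposited tables hold raw UMI counts per gene and cell barcode; per the labels, the submitters' processing notes name Cell Ranger 2.0.1 and Seurat 2.3 and the builds mm10 and hg19 without giving the role of each. The values were checked to be whole numbers of 0 or more. Genes seen in fewer than 3 barcodes of a library are not listed in its table, and how barcodes were chosen is not given in the sources used here.

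The tables were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and clustering used scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0, with figures by matplotlib 3.10.9. Of 16583 barcodes 16041 were kept, with at least 200 genes and at most 10% of UMIs from mitochondrial genes: 3559 of quadriceps, 2940 of diaphragm, 5644 of peritoneal and 3898 of lung cells. No kept or removed barcode had fewer than 359 genes, so the mitochondrial limit alone removed cells. The tables list 13611, 13231, 13296 and 14003 genes in that order, 15570 in any library and 11764 in all of them. Median depth was 4752, 4156, 6407 and 3265.5 UMIs, and the summed depth of the phagocyte cells was 18165678, 13041952, 37164180 and 13318464 UMIs, so that 3 counts stand for 0.165, 0.230, 0.0807 and 0.225 CPM.

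Cells of all libraries were clustered together without batch integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8), and the muscle phagocytes also alone. Clusters were named from fixed marker lists of cell types by their 25 leading genes, and small mixed clusters were clustered again. The naming rule was refined 2 times after clusters had been seen. Clusters matched the lists of alveolar, large peritoneal and class II-high macrophages, monocytes, dendritic cells, proliferating cells, B cells, T cells, fibroblasts, endothelial cells, smooth muscle cells and epithelial cells; the remaining lists named no cluster, and several muscle clusters stayed unnamed. The cluster of 46 cells that the rule named as monocytes, by 3 markers, is led mostly by genes of dendritic and lymphoid cells, such as Cd209a, H2-Oa, Klrd1 and Cd7, so its type is unclear. Phagocyte cells are those outside clusters named as another cell type. They include 2 unnamed clusters whose leading markers are of another type but which kept macrophage genes: 35 cells with neutrophil genes, 32 of them from lung, and joint cluster 5, led by hemoglobin genes. The hemoglobin lead of joint cluster 5 rests mostly on 1 diaphragm cell, with 5430 hemoglobin UMIs. Other leading genes of that cluster include Egr1 and Ccl2. The unclear cluster and the dendritic cell-like one are included too. Scrublet, run through scanpy, called 2, 0, 2 and 0 cells and so did not separate doublets; no doublets were removed, and an alternative removed the highest scores at 0.8% per 1000 cells.

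UMIs were summed over the phagocyte cells of each library and scaled to the library total. With 1 library per tissue no replicate test, p-value or standard error can be given, and no paired analysis was possible because no labels pair the samples. Ratios carry exact Poisson intervals and shares Clopper-Pearson intervals, which cover counting error only. Genes at least 2-fold apart were counted among those with 50 CPM or more in 1 library compared. Where both muscles were set against a reference, a gene had to be 2-fold apart in both in the same direction. That overlap was compared with the product of the separate counts divided by the number of genes, and with 100 draws in which both muscles equalled the reference, which hold counting error only. For ranking, list medians and counts of genes, a count under 3 was set to 3 counts, while printed folds of genes with 1 or more UMIs use the counts themselves. A gene not listed in a library is called not listed and given no fold, but enters list medians and counts of genes at 3 counts.

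The genes named are the 12 highest and 12 lowest per comparison at 50 CPM or more, without mitochondrial, ribosomal protein, sex-linked and predicted genes, together with members of the fixed lists and the sort markers. The 17 fixed lists cover macrophage core, MHC class II presentation, the Lyve1-type resident program, monocyte-derived genes, alveolar and large peritoneal identity, inflammatory cytokines and chemokines, alternative activation, phagocytosis and efferocytosis receptors, growth factors, iron and heme handling, lipid handling, interferon response, immediate early and dissociation stress, cell cycle, matrix and proteases, and complement. Some genes belong to more than 1 list. Each list's median log2 ratio was placed among 10000 random lists of its size matched in 10 bins of expression, as a description. For shares of cells with a gene, each cell was thinned to 2000 UMIs. Gene positions come from GENCODE M21 on GRCm38, in which 3355 of 3446 genes at the floor had 1 position.

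Groups, comparisons, lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. That set held every barcode, a stricter filter (500 genes, 5% mitochondrial UMIs), all cell types, removal of high Scrublet scores, totals without mitochondrial and ribosomal protein genes, median-of-ratios scaling, equal weight per cell, floors of 10 and 200 CPM, thinning to 1000 UMIs or none, other ways to divide cells by Lyve1, and other cluster settings. Alternatives chosen after seeing the data left out hemoglobin genes, the 3 cells with 10 or more hemoglobin UMIs, joint cluster 5, the peritoneal-type cells of the muscles, or both of these groups. The hemoglobin limit, the 5% limit for class II share per cell, the smallest opposite median of 0.1 and the limits for genes far higher in a tissue (200 CPM, 8-fold) were also chosen after seeing the data. The counting was tested on simulated data that held counting error only, with every planted change beyond the 2-fold limit. Of 200 genes changed between quadriceps and diaphragm 100.0% were recovered, 0 unchanged genes reached 2-fold, and 95.0% of intervals covered the true ratio. This checks the counting and says nothing on other differences between libraries. An unchanged simulated list fell between percentiles 2.04 (diaphragm against lung, outside the middle 95%) and 84.02 (quadriceps against peritoneal).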

Results

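Macrophages were sorted from quadriceps and diaphragm, a limb and a respiratory muscle, of C57 BL/6J mice aged 8 weeks, and peritoneal and lung alveolar macrophages were taken as reference populations of a serous cavity and of the airways. Single-cell RNA sequencing in droplets gave 1 library per tissue, so the series holds no replicates and every difference compares libraries. The deposited tables held 3632 barcodes and 18413149 UMIs (unique molecular identifiers, each standing for 1 captured transcript) for quadriceps and 2992 barcodes and 13230675 UMIs for diaphragm. They held 5862 barcodes and 37877735 UMIs for the peritoneal library and 4097 barcodes and 14298839 UMIs for the lung library. The median depth of the cells kept was 4752 UMIs in quadriceps, 4156 in diaphragm, 6407 in peritoneal and 3265.5 in lung cells. Levels are given as CPM, the UMIs of a gene scaled to the total of the phagocyte cells of a library, which numbered 3534, 2921, 5600 and 3720 in the same order. Intervals are 95% exact intervals that cover counting error only.

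The sort markers were present in all libraries. Ptprc (CD45) and the Fc receptor gene Fcgr1 (CD64) were detected in each of them, with Fcgr1 at 205.5 CPM in quadriceps, 168 in diaphragm, 34.4 in peritoneal and 26.4 in lung cells. Adgre1, the gene of F4/80, stood at 687, 609, 745 and 96.6 CPM, and the integrin gene Itgam (CD11b) at 135, 116, 778 and 2.18 CPM in that order, so alveolar cells carried little Itgam transcript. Across 3446 genes the quadriceps and diaphragm libraries were most alike, with a Spearman rank correlation of 0.966. The correlation was 0.709 between quadriceps and peritoneal, 0.694 between diaphragm and peritoneal, 0.454 between quadriceps and lung, 0.460 between diaphragm and lung and 0.489 between peritoneal and lung. These are correlations across genes, which are not replicates, and the order of the last 3 was not kept with a lower expression floor. Clustering put 88.0% of lung cells in an alveolar macrophage-like cluster and 68.0% of peritoneal cells in a large peritoneal macrophage-like cluster, each made almost wholly of 1 library. At resolution 1.2 these shares were 59.8% and 68.8%, and 28.2% of lung cells stayed unnamed. No muscle cell lay in the alveolar-like cluster.

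The first comparison asked how far resident macrophages of a limb muscle and of the diaphragm differ. Immediate early and stress genes were higher in the diaphragm library, with all 20 measured members at least 2-fold higher and a list median of -1.49 (log2 quadriceps over diaphragm), below all 10000 random lists matched on expression. Egr1, a transcription factor gene of the early growth response, stood at 366 CPM in diaphragm and 56.0 in quadriceps, 6.53-fold apart (6.10 to 6.99). Fosb was 5.53-fold (4.94 to 6.22), Atf3 3.90-fold (3.71 to 4.10) and the chaperone gene Dnajb1 3.87-fold (3.64 to 4.11) higher in diaphragm. MHC class II presentation was also higher there, with 5 of 10 members at least 2-fold higher and none lower to that extent (list median -0.98). Cd74, the invariant chain that escorts class II molecules, reached 17249 CPM in diaphragm against 7454 in quadriceps (2.31-fold), and the class II chain gene H2-Ab1 was 2.12-fold higher (2.09 to 2.14). Among inflammatory cytokines and chemokines 9 of 14 were at least 2-fold higher in diaphragm (list median -1.23), including the neutrophil attractant Cxcl2 at 3.87-fold (3.73 to 4.01), Tnf at 2.74-fold (2.41 to 3.14) and Il1b at 2.40-fold (2.18 to 2.65). Ccl5 was the 1 member higher in quadriceps by that measure, at 2.22-fold. Within joint clusters that hold cells of both muscles the class II medians ran from -1.29 to -0.52 and the inflammatory ones from -0.79 to 0.03, and after clustering without stress genes from -1.24 to 0.18 and from -1.01 to 0.01. Class II and cytokine genes were kept in both clusterings, and class II genes led a joint cluster. Smaller medians within clusters can follow from that alone. These values therefore do not tell whether the spread of cells over clusters plays a part.

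Quadriceps cells carried more transcripts of a group of C-type lectin genes that lie close together on chromosome 8. Cd209d (positions 3871824 to 3878555) was 9.11-fold higher (8.00 to 10.4), Cd209b 4.28-fold (3.76 to 4.89), Cd209f 3.30-fold (3.16 to 3.44) and Cd209g 3.10-fold (2.88 to 3.34). These genes are close relatives, so the split of reads among them is uncertain. Also higher in quadriceps were the monocyte attractant Ccl8 (1607 against 446 CPM, 3.61-fold), the water channel gene Aqp1 (5.29-fold), Olfml3 (6.64-fold), the tetraspanin gene Cd9 (3.41-fold), the matricellular gene Spp1 (2.93-fold), the phospholipase gene Pla2g2d (2.65-fold) and the lipid receptor gene Trem2 (2.58-fold). Of 15 interferon response genes 5 were at least 2-fold higher in quadriceps and none lower to that extent (list median 0.53), including Ifit1 at 2.91-fold and Rsad2 at 2.37-fold, while 1 of the 5, Ifi44, was not listed in the diaphragm library. Within joint clusters that hold cells of both muscles the interferon medians ran from -0.47, in the cluster led by Cd209 and interferon genes, to 0.45, and after clustering without stress genes from -0.74 to 0.87, so the direction differs between clusters. Of 13 cell cycle genes 6 were at least 2-fold higher in quadriceps (list median 0.98), with Birc5 at 2.71-fold (2.43 to 3.04) and Ccnb2 at 2.69-fold. Within joint clusters that hold cells of both muscles the cell cycle medians ran from 0.11 to 0.55. The lowest was in joint cluster 10, led by genes of cell division, with 4.89% of quadriceps and 2.14% of diaphragm cells. Cell cycle genes were kept in this clustering, so smaller medians within clusters can follow from that alone. Whether the spread of cells over clusters plays a part in the library difference is not told by these values. The stress, class II and inflammatory medians lay below, and the interferon and cell cycle medians above, all 10000 random matched lists. The macrophage core genes, such as Csf1r and Lyz2, held none of 15 members 2-fold apart (list median 0.20).

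Genes of large peritoneal macrophage identity were higher in diaphragm than in quadriceps, with 14 of 18 members at least 2-fold higher (list median -2.24). Cxcl13, a B cell attractant (chromosome 5, 95956951 to 95961068), had 1620 UMIs in diaphragm and 4 in quadriceps, 564-fold apart (219.9 to 2073). Fibronectin Fn1 was 5.89-fold and the acute phase gene Saa3 4.79-fold higher in diaphragm. A cluster of 37 diaphragm cells, 1.27% of that library (0.893 to 1.74), was large peritoneal macrophage-like and held 1104 of the Cxcl13 UMIs, and 2 quadriceps cells lay in it. Without these cells the list median was -1.32 and Fn1 still stood lower in quadriceps, at -1.32 on the log2 scale. In the other diaphragm cells only Fn1 and Cxcl13, at 44.6 and 40.4 CPM, stood above 10.3 CPM, the level of Itga6. There Prg4 was at 2.19 and Gata6 at 0.392 CPM. The median without these cells thus rests mostly on low levels and is not read as a peritoneal program of other diaphragm cells. Gata6, the transcription factor gene of that cell type, was not listed in quadriceps and had 10 UMIs in diaphragm.

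The remaining lists had medians nearer 0, some with members 2-fold apart in both directions. The median was 0.29 for the Lyve1-type resident program, above all random lists, whose 4 members of 18 at 2-fold or more were Ccl8, Cd209d, Cd209f and Cd209g. The medians were 0.15 for lipid handling, 0.14 for matrix and proteases, 0.10 for phagocytosis and efferocytosis receptors, 0.10 for complement and 0.07 for alveolar identity. They were 0.36 for monocyte-derived genes, -0.05 for growth factors, -0.13 for iron and heme handling and -0.34 for alternative activation, which lay below all random lists. Of 17 growth factors 2 were at least 2-fold higher in quadriceps and 5 in diaphragm, such as Pdgfc (2.01-fold) and Gdf15 (2.34-fold); of 21 matrix genes 2 and 4, such as Mmp14 (4.25-fold) and Mmp12 (3.81-fold); of 11 monocyte-derived genes 2 and 2; and of 15 alveolar genes 2 and 4. The median of all genes was itself 0.14 and became -0.0012 with median-of-ratios scaling, under which the phagocytosis, complement and alveolar medians turned to -0.04, -0.04 and -0.07, so no direction is read from medians of this size.

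In total 88 of 2716 genes at 50 CPM or more were at least 2-fold apart between the muscles, 20 of them higher in quadriceps and 68 higher in diaphragm. The hemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 are among the 68 at 6.74-, 5.09- and 5.22-fold because 1 diaphragm cell held 5430 of 5688 hemoglobin UMIs; without the 3 hemoglobin-rich cells of all libraries their log2 ratios were -0.31, -0.11 and -0.11. A cluster defined in part by immediate early genes held 49.5% of diaphragm and 3.82% of quadriceps cells, and without it 47 genes were 2-fold apart, the stress median was -0.88, and the monocyte-derived, growth factor and iron medians changed sign (-0.18, 0.04 and 0.18), while alternative activation did so without the peritoneal-type cells (0.12).

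**Figure D1:**
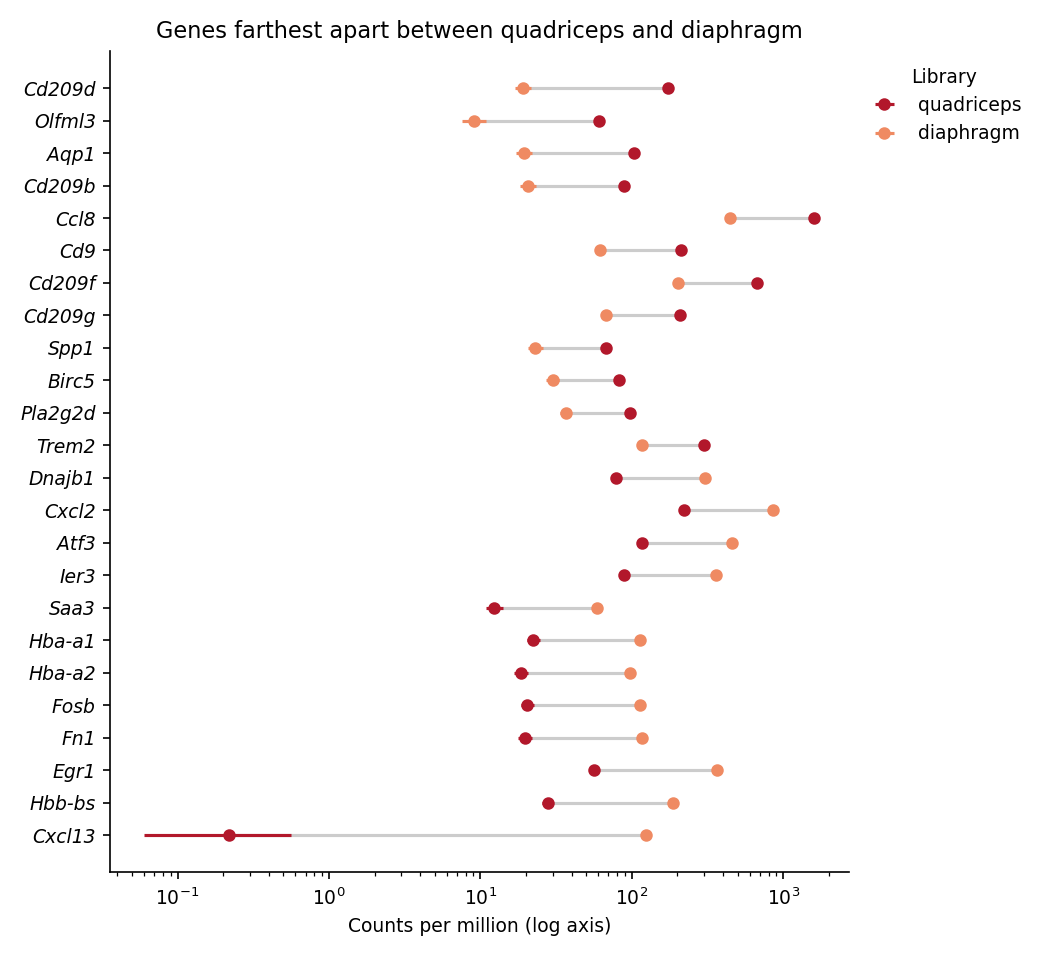
CPM in the quadriceps and in the diaphragm library (log axis) for the genes named by size of their ratio, each with its 95% counting interval. Cd209d is farthest apart toward quadriceps at 9.11-fold and Cxcl13 toward diaphragm at 564-fold. Of the diaphragm Cxcl13 UMIs, 1104 lie in the 37 large peritoneal macrophage-like cells and 516 in other cells. The hemoglobin genes rest on single cells.

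Muscle macrophages were next set against peritoneal macrophages. Chemokine genes were among those most above the peritoneal level. Ccl8 stood at 1607 CPM in quadriceps, 446 in diaphragm and 0.431 in peritoneal cells, 3734-fold (2299 to 6533) and 1035-fold (637 to 1813) apart, and Ccl12 and Ccl7 were 1342- and 459-fold higher in quadriceps and 1161- and 683-fold higher in diaphragm. The iron exporter gene Slc40a1 was 1104-fold (473 to 3404) and 723-fold (309 to 2231) higher, the orphan receptor gene Gpr34 433- and 397-fold, and the membrane protein genes Ms4a6b and Ms4a7 557- and 651-fold in quadriceps and 470.4- and 337-fold in diaphragm. Slco2b1, Cyr61, Serpinf1, Cxcl10 and Pla2g2d were not listed in the peritoneal library. The fractalkine receptor gene Cx3cr1 was at 249 and 169 CPM in the muscles and 1.29 CPM in peritoneal cells.

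Genes of large peritoneal macrophage identity were lower in both muscles, with all 18 members at least 2-fold lower (list medians -8.88 in quadriceps and -6.42 in diaphragm). Gata6 was at 93.3 CPM in peritoneal cells and 122-fold lower in diaphragm (66.1 to 254). The lubricin gene Prg4 was 1937- and 134-fold lower, the lipoxygenase gene Alox15 1482- and 120.1-fold, the protease inhibitor gene Slpi 5355- and 156-fold, and the coagulation factor gene F5 1244- and 149-fold lower in quadriceps and diaphragm. Prtn3, Tgfb2, Ptgis, Ltbp1, Padi4, Nfe2 and Hp completed the 12 furthest below the peritoneal level. The diaphragm ratios contain the 37 peritoneal-type cells described above.

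List medians above the peritoneal level in quadriceps and diaphragm were 2.93 and 3.70 for MHC class II presentation, 4.57 and 5.94 for inflammatory cytokines and chemokines, 4.02 and 3.69 for the Lyve1-type program, 2.32 and 1.72 for interferon response, 2.76 and 2.54 for growth factors, 1.88 and 2.00 for matrix and proteases and 1.29 and 2.49 for alternative activation. Of the 18 Lyve1-type genes 12 were at least 2-fold higher in both muscles, such as the scavenger receptor gene Cd163 (456 and 578 against 22.4 CPM), and 3 were lower in both, namely Timd4, Fcna and Vsig4. Immediate early genes were higher too, by 2.62 and 3.88, with 15 of 20 members at least 2-fold higher in both muscles. This list also holds genes of dissociation stress, and how peritoneal and lung cells were obtained is not given separately. In every comparison with these libraries, isolation therefore cannot be told apart from tissue for immediate early, inflammatory and chemokine genes. Smaller medians were found for macrophage core (0.96 and 0.76), iron and heme handling (0.99 and 0.82), phagocytosis receptors (0.56 and 0.40) and complement (0.52 and 0.46). Alveolar identity genes had medians of 1.77 and 2.24 from levels of mostly a few CPM, and monocyte-derived genes -0.75 and -1.18. The cell cycle medians pointed in opposite directions, 0.65 and -0.31, and lipid handling, at 0.10 and 0.29, turned to -0.21 in quadriceps with median-of-ratios scaling. Without joint cluster 5 the diaphragm cell cycle median changed sign.

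Of 2939 genes 475 were at least 2-fold higher and 217 at least 2-fold lower in both muscles, 692 in all, of which 68.6% were higher. With median-of-ratios scaling the counts were 366 and 306, so that 54.5% were higher, and the median of all genes moved from 0.28 to -0.04 in quadriceps and from 0.12 to -0.06 in diaphragm. In quadriceps alone 574 genes were higher and 234 lower, and in diaphragm alone 523 and 247, so that independent lists would share 102 and 19.7. Simulated unchanged muscles shared at most 0 in 100 draws, which hold counting error only, too small at this depth for 2-fold changes, so this 0 says nothing on other differences between libraries; part of the observed overlap may come from the shared peritoneal library.

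Against lung alveolar macrophages both muscles carried far more transcripts of the complement component genes C1qa, C1qb and C1qc, which lie side by side on chromosome 4. C1qa stood at 6903 CPM in quadriceps, 6394 in diaphragm and 5.56 in lung cells, 1242-fold (989 to 1582) and 1151-fold (917 to 1466) apart. The folate receptor gene Folr2 was 2499-fold (1358 to 5211) and 1854-fold (1008 to 3867) higher, Ccl8 5352- and 1484-fold, the resistin-like gene Retnla 1604- and 1479.6-fold, the ficolin gene Fcna, with 2 UMIs in lung cells, 2647-fold (732 to 21859) and 1692-fold (468 to 13974), Ccl24 1279- and 1072-fold, Tmem37 922- and 959-fold, and the hyaluronan receptor gene Lyve1 924- and 1209-fold. Fxyd2 and Cd209f were not listed in the lung library.

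Alveolar identity genes were lower in both muscles, with all 18 members at least 2-fold lower (list medians -8.38 and -8.70, with members not listed set to 3 counts). The chitinase-like gene Chil3 reached 13209 CPM in lung cells against 4.73 in quadriceps and 3.68 in diaphragm, 2790.0-fold (2259 to 3488) and 3589-fold (2707 to 4868) apart. Ear1 was 4275- and 3069-fold lower. The fatty acid binding gene Fabp1 (1201 CPM in lung cells), Krt79 and the lipid droplet gene Cidec were not listed in either muscle, and Plet1, Car4, Acaa1b, Wfdc21 and the coagulation factor gene F7 were listed in quadriceps at 3 to 6 UMIs and not in diaphragm, while Krt19 was listed in diaphragm at 7 UMIs and not in quadriceps. Scgb1a1, a secretory product of airway epithelium, was 1455- and 1974-fold lower in the muscles. Epithelial-like cells, 0.590% of lung cells, carried it at 403614 CPM and are left out of the sums. Whether free RNA of such cells gave the Scgb1a1 in the lung sum was not tested, so it is not read as a gene of alveolar macrophages. Lipid handling genes were lower as well, with 14 of 20 at least 2-fold lower in both muscles (list medians -3.55 and -3.38).

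List medians above the lung level were 9.68 in quadriceps and 9.23 in diaphragm for the Lyve1-type program, 7.35 and 6.96 for complement, 4.85 and 3.77 for interferon response, 3.53 and 4.28 for MHC class II presentation, 2.62 and 2.60 for phagocytosis receptors, 1.88 and 1.88 for iron and heme handling, 1.19 and 1.59 for macrophage core and 1.06 and 2.04 for alternative activation. Monocyte-derived genes stood at -1.17 and -2.97, with 4 of 11 members at least 2-fold higher in both muscles, among them Ccr2 (136 and 171 CPM), and 6 lower, among them Chil3, which is also an alveolar identity gene, and Plac8, which 32 neutrophil-like cells kept in the lung sum carry. Matrix and proteases were at -0.54 and -0.34. Peritoneal identity genes had medians of 0.29 and 1.94, the first of which turned to -0.42 when cells of other types were included. Inflammatory genes were at -0.68 and 0.03, growth factors at 0.51 and -0.21, immediate early genes at -0.27 and 1.43 and cell cycle genes at 0.24 and -1.01, the quadriceps value of the last turning to -0.03 with median-of-ratios scaling.

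Of 3313 genes 595 were at least 2-fold higher and 561 at least 2-fold lower in both muscles, 1156 in all and 51.5% higher, against 497 and 718 (40.9% higher) with median-of-ratios scaling, which moved the median of all genes from -0.0043 to -0.28 in quadriceps and from -0.15 to -0.28 in diaphragm. Quadriceps alone gave 686 higher and 621 lower and diaphragm alone 630 and 645, and independent lists would share 130.4 and 121. Simulated unchanged muscles shared at most 0, again from counting error only and so no measure of the shared library, and part of the excess may come from the shared lung library.

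The reference populations were also set against each other, as a scale for the muscle comparisons. Peritoneal cells carried Prg4 at 3092 CPM and lung cells at 2 UMIs, 20588-fold apart with a wide interval (5699 to 170000.0). Saa3 was 10733-fold, Fcna 9601-fold, Alox15 5589-fold, Cxcl13 3718-fold, the endothelin receptor gene Ednrb 1968-fold and Ccl24 1725-fold higher in peritoneal cells. Cd5l, Prtn3, Vsig4, Padi4 and F5 were not listed in the lung library. Lung cells carried Ear2 at 2810.3 CPM, 2048-fold higher (1557 to 2751), and the proton pump gene Atp6v0d2 3791-fold higher. The airway epithelium gene Scgb1a1 was 6328-fold higher in the lung sum, with the limit on its source given above. Plet1, Fabp1, Ear1, Car4, Krt19, Acaa1b, Krt79, the cathepsin gene Ctsk and Cidec were not listed in the peritoneal library. All 18 peritoneal identity genes were at least 2-fold higher in peritoneal cells (list median 8.00) and 17 of 18 alveolar identity genes at least 2-fold lower (-11.25).

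Medians were above 0 against lung cells for complement (list median 7.94), the Lyve1-type program (5.56), interferon response (2.06), monocyte-derived genes (1.72), phagocytosis receptors (1.22), MHC class II presentation (0.58, with 2 members at least 2-fold higher and 3 lower) and macrophage core (0.38), the last 2 within the middle 95% of random lists. They were below 0 for inflammatory genes (-4.04), immediate early genes (-2.64), matrix and proteases (-2.22), lipid handling (-1.67), growth factors (-1.49), iron and heme handling (-0.93) and cell cycle (-0.51, within the middle 95% of random lists), and alternative activation was at -0.10, also within it, turning to 0.02 when mitochondrial and ribosomal protein genes were left out of the totals. Of 2963 genes 1175 were at least 2-fold apart, 395 higher and 780 lower in peritoneal cells, and the median of all genes was -0.24.

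**Figure D2:**
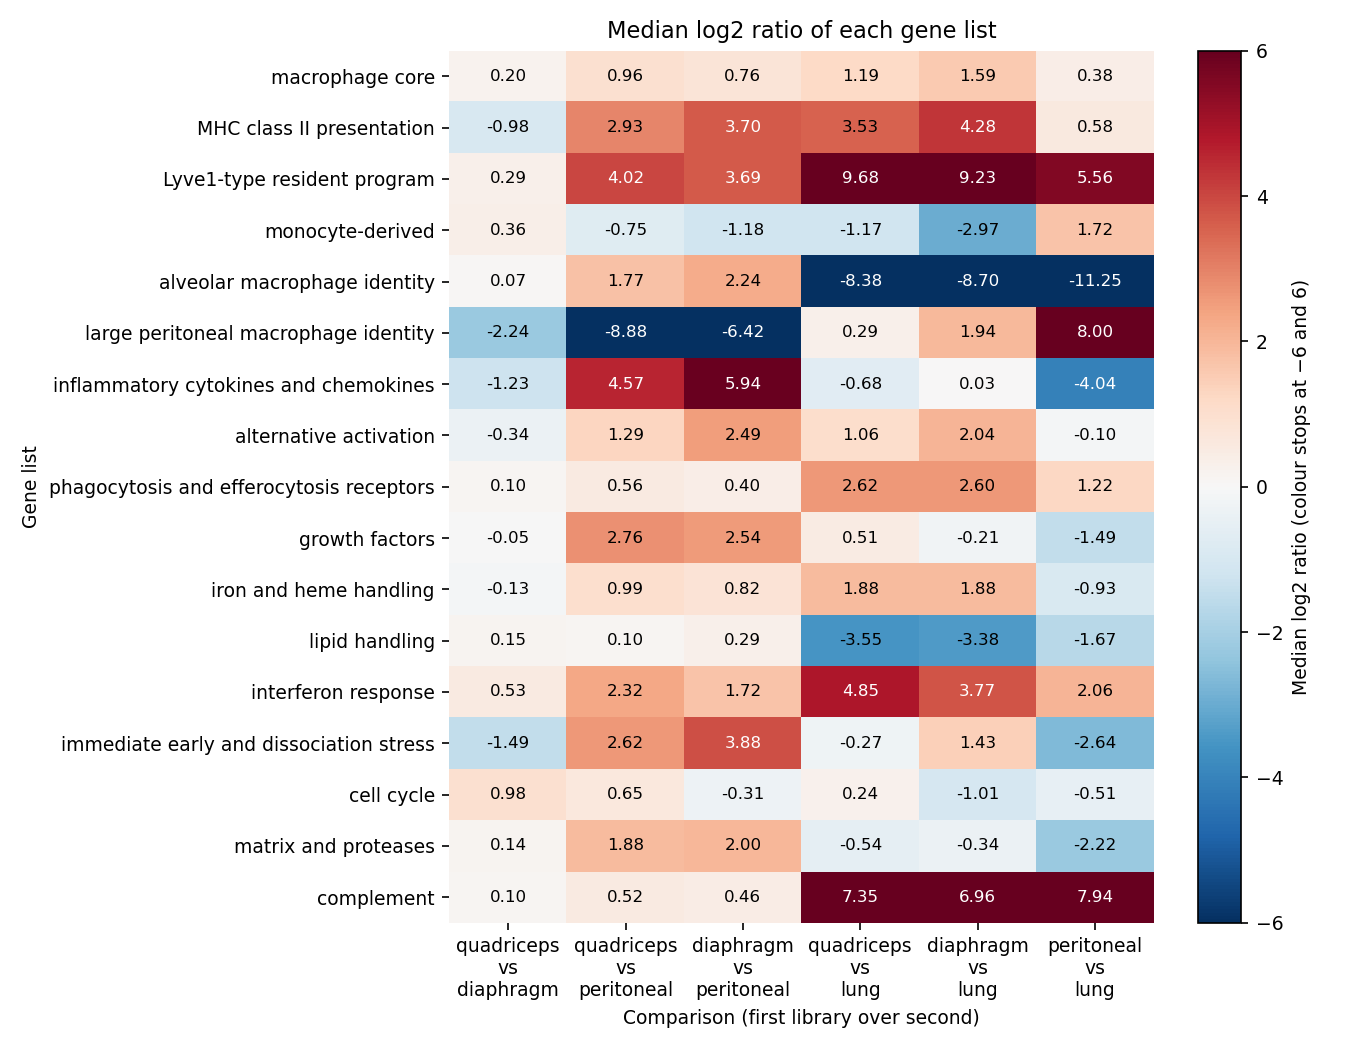
Median log2 ratio of each fixed gene list (vertical) in each pair of libraries (horizontal), coloured and printed, first library over second. The stress list stands at -1.49 between quadriceps and diaphragm, and the alveolar list at -8.38 and -8.70 against lung.

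The muscle libraries were then divided by Lyve1, a hyaluronan receptor gene used as a marker of one type of resident tissue macrophage (chromosome 7, 110850607 to 110863239). With every cell thinned to 2000 UMIs, 55.1% of quadriceps cells (53.4 to 56.8; 1861 of 3376, with 158 shallower cells left out) and 61.0% of diaphragm cells (59.2 to 62.8; 1712 of 2805, with 116 left out) had a Lyve1 UMI. The level was 625 CPM in quadriceps and 817 in diaphragm. The share was 8.72% in peritoneal and 0.128% in lung cells, and without thinning it was 72.1, 73.2, 15.4 and 0.188% in quadriceps, diaphragm, peritoneal and lung cells. In fibroblast-like cells, taken to lack the gene, 0 of 10 quadriceps cells (median 4749 UMIs) and 1 of 12 diaphragm cells (1 shallower cell left out, median 5449 UMIs over all 13) had a Lyve1 UMI after thinning, too few to set the background in the muscles. H2-Ab1, a class II gene, had a UMI in 7 of these 10 and 5 of these 12 cells, so sharing of Lyve1 and class II transcripts by a cell is not read from these data.

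MHC class II transcripts were lower in cells with Lyve1. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 made up 1.02% of UMIs in quadriceps cells with Lyve1 and 2.86% in those without, 2.81-fold apart (2.79 to 2.83). In diaphragm they made up 2.17% and 6.38%, 2.93-fold apart (2.92 to 2.95). When thinned cells were divided into 4 groups of equal size by their class II share, Lyve1 was found in 63.6% of the lowest and 31.2% of the highest group in quadriceps and in 82.8% and 25.7% in diaphragm. Per cell, class II genes had a median share of UMIs of 0.247% in quadriceps and 1.62% in diaphragm, and 12.0% and 29.99% of cells reached 5% or more, a limit near which many cells lay (214 and 300 cells between 4 and 6%).

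**Figure D3:**
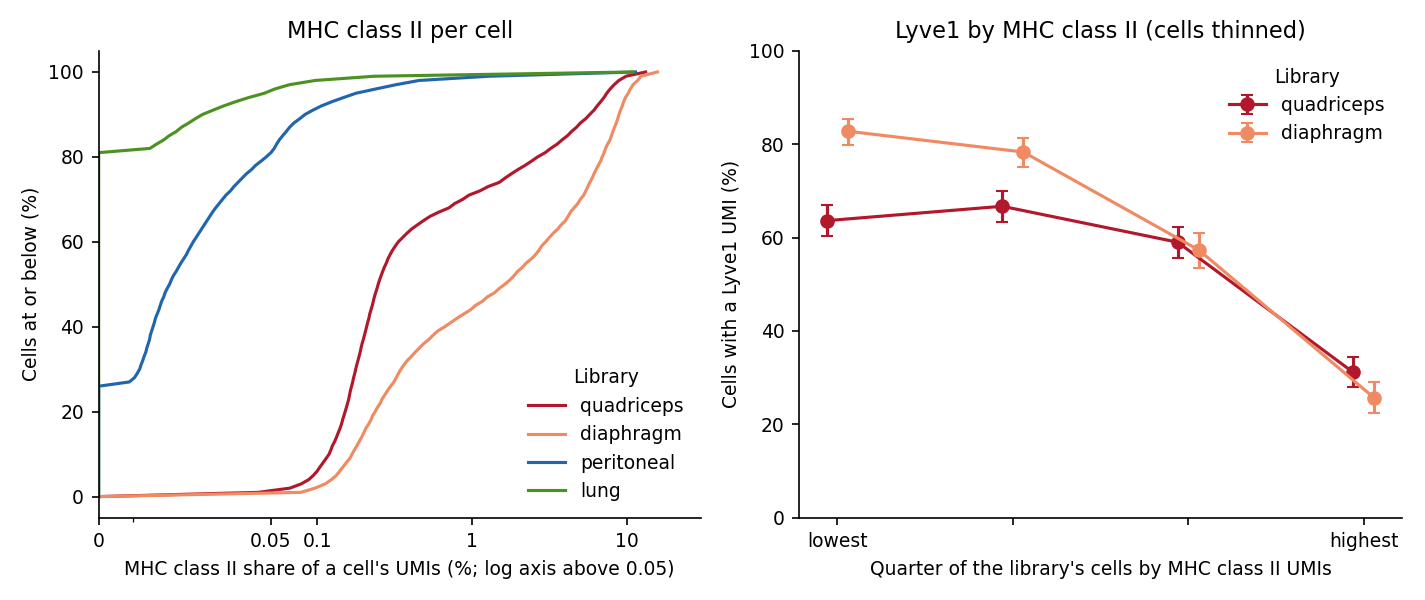
Share of each cell's UMIs from H2-Aa, H2-Ab1, H2-Eb1 and Cd74 by percent of cells in each library (log axis), and percent of muscle cells with a Lyve1 UMI after thinning in 4 groups of cells ranked by that share, with 95% exact intervals. Lyve1 was found in 31.2% of quadriceps and 25.7% of diaphragm cells of the highest group.

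In both muscles cells with Lyve1 carried more Ednrb (3.88-fold in quadriceps and 4.16-fold in diaphragm), Fcna (3.28 and 4.29), the phosphatidylserine receptor gene Timd4 (3.12 and 3.00), the fibroblast growth factor receptor gene Fgfr1 (2.96 and 3.01), Cd209f (2.93 and 4.57), the leukotriene synthase gene Ltc4s (2.61 and 3.97), Cd209g (2.55 and 3.74) and Cd209b (3.20 and 2.49). Hba-a1, Hba-a2, Hbb-bs and Hbb-bt ranked among the 12 highest because of 1 hemoglobin-rich cell per muscle library. Cells without Lyve1 carried more Ccr2, the receptor that draws monocytes into tissue (3.84-fold, 3.54 to 4.16, in quadriceps and 5.30-fold, 4.85 to 5.79, in diaphragm), Spp1 (4.19 and 16.2), Tnip3 (4.41 and 7.98), Il1b (3.54 and 4.84), Alox15 (3.43 and 4.44), Gngt2 (4.05 and 3.43), Bcl2a1d (3.20 and 3.56), Axl (3.29 and 3.14), Ccnd2 (3.55 and 3.12), Bcl2a1a (3.01 and 5.05), Tmem119 (4.03 and 2.91) and Cd74 (2.93 and 2.93). The diaphragm value of Alox15 rests mostly on the peritoneal-type cells, which hold 282 of its 319 UMIs there.

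Of 2850 genes 27 were at least 2-fold higher and 42 at least 2-fold lower with Lyve1 in both muscles. The list medians, with over without Lyve1, were -1.38 in quadriceps and -1.54 in diaphragm for MHC class II, -1.20 and -2.29 for monocyte-derived genes, -1.33 and -0.65 for inflammatory genes and 1.05 and 1.22 for the rest of the Lyve1-type program, of which 10 and 11 of 17 measured members were at least 2-fold higher. Among monocyte-derived genes Ccr2 and Ms4a4c were lower with Lyve1 in both muscles and S100a4 was within 2-fold. Macrophage core genes were at 0.02 and 0.01 and complement at 0.24 and 0.41. Cells with a Lyve1 UMI are deeper on average, and with thinned cells 11 genes were higher and 31 lower.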

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

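The tests of cell mix and of sex were chosen only after the result was seen, while the test of handling was written before. Some list medians of the muscles pointed in opposite directions against the same reference library, and these differences between the muscles were not tested. Against lung cells, growth factors were at 0.51 in quadriceps and -0.21 in diaphragm, with Gdf15 and Grn among the members, and immediate early genes at -0.27 and 1.43. Cell cycle genes such as Top2a and Birc5 were at 0.65 and -0.31 against peritoneal cells and at 0.24 and -1.01 against lung cells. The diaphragm cell cycle value against peritoneal cells changed sign when the cluster defined in part by immediate early genes was left out. Its direction therefore depends on that cluster. With median-of-ratios scaling the quadriceps cell cycle value against lung cells turned to -0.03, so both muscles then pointed the same way.

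Cells of other types, which the comparisons do not use, were present in each library, at 0.702% in quadriceps, 0.646% in diaphragm, 0.780% in peritoneal and 4.57% in lung cells. In lung they were T cell-like (52 cells), fibroblast-like (38 cells), B cell-like (34 cells), epithelial-like (23 cells), endothelial-like (17 cells) and smooth muscle-like (14 cells). In peritoneal cells 41 were B cell-like, and in the muscles 10 quadriceps and 13 diaphragm cells were fibroblast-like.

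Immediate early and stress genes stood higher in diaphragm than in quadriceps (list median -1.49). A different mix of cell groups is argued against as the whole cause: with muscle cells clustered without these genes, the median over 8 clusters was -0.89, and each of them lay between -1.40 and -0.38. In joint clusters that hold cells of both muscles, for which these genes were kept, the list medians ran from -1.27 to -0.16. The weakest value lay in joint cluster 3, with 1791 quadriceps and 424 diaphragm cells. Smaller medians in these joint clusters can follow from keeping the genes. The clusters formed without the genes also gave medians smaller in size than -1.49. Part of the difference may therefore reflect how cells are spread over clusters. The list was at -1.27 among cells with Xist and at -2.02 among cells with Y-linked transcripts. The class II list was at -0.91 and -1.16 and the inflammatory list at -0.96 and -1.34 in the same cells. These values argue against a difference in the sex of the animals only as far as such transcripts mark the sex of a cell. Free RNA or paired cells as their source could not be told apart from pooling, so the question of sex stays open. Handling that stressed every cell type of the diaphragm sample cannot be told apart from a tissue difference, because the fibroblast-like cells gave 0.0269 from 10 and 13 cells and leaving out 1 cell moved this between -0.23 and 0.40. A difference between the muscles as tissues was not tested apart from handling and stays open.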

How the results depend on the processing

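Alternatives without joint cluster 5, peritoneal-type cells, hemoglobin genes or hemoglobin-rich cells were chosen only after the result was seen; the others were planned. Under the 7 planned settings other than the CPM floor, genes at least 2-fold apart numbered 82 to 95 between the muscles, 672 to 766 for both muscles against peritoneal, 1148 to 1325 against lung and 1164 to 1390.0 for peritoneal against lung. By construction the floor sets how many genes are counted: these were 211, 1523, 2540.0 and 2556 at 10 CPM and 38, 273, 372 and 399 at 200 CPM. Of 2948 alternative values 17 reversed, and 0 planned ones did, where only list medians outside the middle 95% of random lists were checked. Among medians nearer 0, planned settings turned alternative activation between peritoneal and lung (0.02), alveolar (-0.07), complement (-0.04) and phagocytosis (-0.04) between the muscles, cell cycle (-0.03) and peritoneal identity (-0.42) in quadriceps against lung, inflammatory genes in diaphragm against lung (-0.10) and lipid handling in quadriceps against peritoneal (-0.21). Floors leave list medians unchanged by construction.

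Without joint cluster 5, which selects on immediate early genes, 47 genes were 2-fold apart between the muscles, monocyte-derived genes were at -0.18, growth factors at 0.0377, iron and heme handling at 0.18, cell cycle in diaphragm against peritoneal at 0.31, and Hbb-bs, Hba-a2 and Hba-a1 at 1.77, 2.65 and 2.73. Without peritoneal-type cells as well these were 48 genes, -0.16, 0.039, 0.17, 0.29, 1.75, 2.63 and 2.71. The hemoglobin values turned because the diaphragm cell rich in hemoglobin is removed and the quadriceps one is not. For the rest the cause was not tested. Alternative activation was at 0.12 between the muscles without peritoneal-type cells. Without the hemoglobin-rich cells Hba-a2 and Hbb-bt were at -0.017 and -1.76 with over without Lyve1. The rank correlation at a floor of 10 CPM was 0.793 (quadriceps) and 0.789 (diaphragm) with peritoneal, 0.633 and 0.640 with lung and 0.636 between peritoneal and lung, and 0.408 for diaphragm and lung without mitochondrial, ribosomal protein and immediate early genes. Shares with Lyve1 follow the depth by construction: 38.3% and 46.7% at 1000 UMIs, 72.1% and 73.2% without thinning. The class II ratio was 3.98 and 3.69 with 2 or more Lyve1 UMIs and 2.67 and 2.86 in thinned cells, in which 42 genes were 2-fold apart by Lyve1 (11 higher, 31 lower). Other cell types made up 1.45% of peritoneal and 5.72% of lung cells at resolution 0.4, and 5.62% of lung cells at 1.2 and 5.57% without immediate early genes. Cells in class II-high clusters made up 24.5% (0.4), 22.1% (1.2) and 15.5% (without Lyve1 and class II genes) of quadriceps, and 79.8% (0.4), 36.0% (1.2) and 40.6% (without immediate early genes) of diaphragm; the cause was not tested. The rule also named Lyve1-type clusters at these resolutions, with 69.8% (0.4) and 37.7% (1.2) of quadriceps against 17.0% and 12.2% of diaphragm, opposite to the order by Lyve1 UMIs, so no share of a cell type is read from cluster names.

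Of the other planned values 670 of 918 list medians and 622 of 864 named gene ratios stayed within 0.1 log2 units of the main value. By the same limit 42 of 48 gene ratios by Lyve1 moved. Of the class II ratios by Lyve1, 4 of 4 moved outside the counting interval of the main value. Genes near 3 counts are limited by depth, which differed between libraries (13318464 UMIs in lung and 37164180 in peritoneal phagocytes).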

Other observations

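The test of free RNA in the diaphragm library was chosen only after the result was seen, in place of an earlier one, and so was the spread from redrawn cells by which paired cells and carry-over are read. After thinning, Folr2 was found in 88.6% of quadriceps, 77.8% of diaphragm, 13.5% of peritoneal and 0.064% of lung cells, and the mannose receptor gene Mrc1 in 84.2, 79.4, 6.58 and 68.7%. Timd4 was found in 21.3, 24.9, 66.2 and 0.321% and Ccr2 in 13.8, 15.9, 3.57 and 0.739% in the same order; no background share was set for these genes. Proliferating-like cells made up 6.62% of quadriceps and 3.49% of diaphragm phagocytes when the muscles were clustered alone.

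Hmox1 and Plin2 stood highest, and Apoe lowest, in alveolar cells among the 4 libraries, while the iron and heme list as a whole was higher in both muscles than in lung (list medians 1.88 and 1.88). The heme oxygenase gene Hmox1 stood at 2670.1 CPM in lung, 417 in quadriceps, 525 in diaphragm and 72.8 in peritoneal cells, and the lipid droplet coat gene Plin2 at 1983, 212, 249.6 and 201 CPM. Apoe, the lipid carrier gene, stood at 126 CPM in lung cells and 21305, 23003 and 18966 in quadriceps, diaphragm and peritoneal cells.

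The 37 large peritoneal macrophage-like cells of the diaphragm library carried Prg4 at 976 CPM against 2.19 in other diaphragm cells and 3092 in peritoneal cells, Fn1 at 3391, 44.6 and 7332 CPM, Thbs1 at 601, 5.56 and 541 CPM, and Cxcl13 at 3949, 40.4 and 838 CPM, with 100 or more Cxcl13 UMIs in each of 6 of these cells. Thbs1 and Cxcl13 were the only peritoneal identity genes above the peritoneal level. The others lay below it, such as Gata6 at 17.9 against 93.3 CPM and Slpi at 851 against 4127 CPM. Leading genes of the cluster, with its 2 quadriceps cells, were found in 12.8% (Slpi) to 66.7% (Prg4) of cells. Index hopping is argued against, since 0.0% of their barcodes were also peritoneal barcodes (up to 9.49). Droplets that pair a muscle and a peritoneal macrophage cannot be told apart from single cells: genes far higher in diaphragm lay at 29.4% of the diaphragm level (21.8 to 36.7 on redrawing cells), above the bound set for paired cells but with that bound inside the spread, 33 of the 37 cells lay between the ranges of peritoneal and other diaphragm cells for these genes (3 in the peritoneal and 1 in the diaphragm range), and their median was 6532 UMIs against 4141.5 in other diaphragm cells and 6414.5 in peritoneal phagocytes. For free RNA of the suspension, genes far higher in peritoneal cells stood in the other diaphragm cells at 0.182% of their level in these 37 cells (0.109 to 0.374). Clustering had set the 37 cells apart with peritoneal genes in the lead, so a low value was favoured in advance. It speaks only against RNA spread evenly over droplets as the source of the level in these cells. Free RNA as a source of part of the peritoneal transcripts stays open. The earlier test, at 45.8% of the peritoneal level (28.1 to 60.2), lay between its bounds. Carry-over of cavity cells when the diaphragm was taken could equally leave such cells, and it cannot be told apart from residence on the diaphragm surface. The rank correlation across genes was 0.745 with the large peritoneal macrophage-like cluster of the peritoneal library, 68.0% of its cells. It was 0.752 with all other diaphragm phagocytes, which met the bound against carry-over by less than its spread (-0.0562 to 0.0468). The remaining peritoneal cells were not compared.

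Xist and Y-linked transcripts occurred in every library. Cells with Xist alone made up 54.7% of quadriceps, 68.2% of diaphragm, 40.8% of peritoneal and 46.0% of lung phagocytes, and cells with Y-linked transcripts alone 15.7, 9.86, 22.6 and 20.3%. Both met in 688 cells where independence gives 1856, a ratio of 0.371, so a candidate explanation is that animals of both sexes were pooled. By library the ratio was 0.4055 in quadriceps, 0.2186 in diaphragm, 0.4595 in peritoneal and 0.2619 in lung cells. Free RNA or paired cells as the source of part of these cells cannot be told apart from pooling, because the ratio over all libraries lies between the bounds set. The labels used here give no sex.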
